A study of Mus musculus with 18 samples.

How the data were processed

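RNA was taken from suspended cells of mouse bone marrow and spleen with the SPLIT kit and made into QuantSeq forward libraries, per the labels' protocols. QuantSeq primes on the poly(A) tail, so each transcript gives tags from its 3' end and the count does not scale with its length. There were 18 libraries, 8 of bone marrow (4 Cgas-/- and 4 dKO) and 10 of spleen (5 dKO recipients of Cgas-/- marrow and 5 of dKO marrow, taken 12 weeks after transplantation). Each library was placed in its group by its label. The labels call the libraries separate samples without saying that each is from another mouse, so the p-values measure only the spread between these samples, which may be technical.

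The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.6.1, Partek and DESeq2, and the genome build mm10. The version of DESeq2, the counting tool, the annotation, the counting strand and the filter on genes are not given in the sources used here. The files used were 2 tables, 1 per tissue, in which the authors had already compared the groups with DESeq2, per the file headers. The mean normalized count of each gene is a signal averaged by the authors over the libraries of the comparison, after division by size factors, per the file headers. The log2 fold change and its standard error are the authors' DESeq2 estimates, per the file headers, and the direction of each was taken from the tables' names and from Cgas and Trex1. The Wald score is the authors' log2 fold change divided by its standard error, as deposited, and a ranking score is the authors' log2 fold change times minus the decimal logarithm of the p-value. The p-value is the authors' normal p-value of the Wald score, as deposited, and the adjusted p-value is the Benjamini-Hochberg value over the genes of the table. These relations were checked by recomputing them from the deposited values. Values per library were not used here, so the depth of each library is unknown and no count test was run.

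The tables differ in how they were made. The smallest mean normalized count was 6.46 in the bone marrow table and 0.239 in the spleen table, so the first lists no gene with a mean as low as many in the second. The bone marrow table held 14423 genes, of which 12045 had a mean of at least 20, and the numbers for spleen were 21830 and 11118. In the bone marrow table, 27 genes shared all values with another gene, 6 of them called. The gene with the highest mean held 13.9% of the summed means in bone marrow and 2.50% in spleen. Symbols were matched to GENCODE M21 (GRCm38, the assembly of mm10), which gave 14281 direct matches, 56 by synonym and 86 unmatched in bone marrow, and 21678, 31 and 121 in spleen. Coordinates are from that annotation, counted from 1.

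The authors' log2 fold changes, standard errors and adjusted p-values were used as deposited, with a threshold of 0.05. The genes named in the text follow a rule fixed before the data were examined. It takes the targeted genes, the 6 genes with the largest change in each direction among those past the threshold with a mean of at least 20 (without clone names), and the 2 members with the smallest adjusted p of each list with a call. For the difference between tissues it takes the 6 genes with the largest z in each direction. Genes named outside the rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here, and the counts include them. The 29 gene lists, of pathways and of cell types that bone marrow and spleen hold, were written from general knowledge before the data were examined. Each list with at least 5 measured genes was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald scores, called camera in the text, with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. A correlation estimated from the data needs values per library and was not computed.

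The difference between tissues was the spleen minus the bone marrow log2 fold change, over the root of their summed squared standard errors, for 13853 genes, with a two-sided normal p adjusted by Benjamini-Hochberg, and lists were tested on that z with cameraPR. The comparisons share no library. The tables were normalized separately, so mean levels are not compared across them as measurements. Overlap of calls was tested with Fisher's exact test, two-sided. Genes within 10 Mb of Trex1 or Cgas are called near them. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, figures matplotlib 3.10.9, and the matching of pseudogene transcripts blastn 2.17.0.

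The steps were tested on simulated data made with the deposited means and standard errors, with 200 genes changed in each of 20 runs. The changed genes were all drawn from those with a mean of at least 20, so recovery below that mean was not tested. With the 14423 genes of the bone marrow table, 81.7% of genes changed by 1 on the log2 scale and 98.6% of those changed by 2 were recovered, and 4.55% of calls were false. With the 21830 genes of the spleen table these were 88.7%, 98.8% and 4.44%. The interferon-stimulated list, with 69 measured genes and shifted by 0.3, was recovered in 20 of 20 runs for each table. Other lists and smaller shifts were not tried. Errors were drawn independently for each gene, so correlation between genes was not checked. This test assumes the deposited standard errors, so it does not check them. Other thresholds, filters, scalings, statistics and correlations were tried, and the closing section gives their effect.

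Named genes that share sequence or position with others are uncertain, since the authors' counting could split or merge their reads. These are the paralogs among Oas, Ear, globin, histone and H2 genes, Rpl29 with its processed pseudogenes, Trex1 with Atrip and Rtp4 with Gm45338 on the same strand. Bfsp2, Cgas, Col6a4, Junb, Ms4a4c, Rassf1, Tma7, Vpreb1, Wdfy1, Wdfy4 and mt-Tq overlap a gene on the opposite strand.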

Results

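Gene expression was measured in cells dissociated from mouse bone marrow and spleen by QuantSeq, a 3' mRNA sequencing method that reads a transcript only near its polyadenylated end. The mice were C57BL/6, of 2 genotypes that interrupt the cytosolic DNA response at different steps. Cgas-/- cells lack cGAS, the DNA sensor that makes the second messenger cGAMP, and carry TREX1 and the cGAMP receptor STING. Cells of the other genotype, called dKO, lack TREX1, an exonuclease that degrades cytosolic DNA, and carry the goldenticket allele of Sting1, which leaves no functional STING. Bone marrow was compared between 4 Cgas-/- and 4 dKO libraries. Spleen was compared between 5 libraries from irradiated dKO recipients of Cgas-/- marrow and 5 from dKO recipients of dKO marrow, 12 weeks after transplantation. The series title gives the question behind the spleen comparison, whether cGAMP made in Trex1-deficient tissue acts on other cells. The data used here were the authors' deposited table of DESeq2 results for each tissue, with 14423 genes for bone marrow and 21830 for spleen. The depth per library is unknown from these tables. Mean normalized counts summed to 9.71e+06 over the genes of the bone marrow table and to 4.56e+06 over those of the spleen table. In the authors' deposited tables the median standard error of a log2 fold change was 0.166 in bone marrow and 0.139 in spleen for genes with a mean normalized count of at least 20, and 0.614 and 0.835 below that. All fold changes are Cgas-/- relative to dKO, or Cgas-/- marrow relative to dKO marrow.

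The targeted genes were read first. In the authors' deposited table for bone marrow, Cgas was 2.18-fold lower in Cgas-/- cells, with a log2 fold change of -1.13 ± 0.155 (standard error, as throughout) and a DESeq2 adjusted p of 6.99e-10. Trex1 was 2.73-fold higher there, at 1.45 ± 0.178 in the authors' deposited table (DESeq2 adjusted p = 7.93e-13). For spleen, the authors' deposited table gave -0.92 ± 0.217 for Cgas (DESeq2 adjusted p = 0.0176) and 2.71 ± 0.199 for Trex1, a 6.55-fold difference (DESeq2 adjusted p = 8.48e-39). Sting1, listed under its older symbol Tmem173, had log2 fold changes of -0.13 ± 0.176 in bone marrow and -0.02 ± 0.0751 in spleen in the authors' deposited tables, and neither passed the test. Genes of the cGAS and STING pathway as a list passed in neither tissue (median 0.05 and adjusted p = 0.633 in bone marrow, -0.03 and 0.498 in spleen, by camera, where the direction of the spleen test is upward and turns downward with ranks), and Cgas and Trex1 were its only calls in the authors' deposited tables. The goldenticket allele is a point mutation, so the Sting1 level checks nothing, and 3' tags outside the deleted parts of Cgas and Trex1 can still be counted. On GRCm38, Trex1 lies on the minus strand of chromosome 9 at 109057933 to 109059734, Cgas on the same strand at 78430526 to 78443237, and Sting1 on chromosome 18 at 35733679 to 35740554. Trex1 overlaps Atrip on the same strand, so reads of these genes cannot be fully separated.

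The bone marrow comparison asks how untransplanted marrow of the 2 genotypes differed. Interferon-stimulated genes were lower in Cgas-/- cells, by a median of -0.31 on the log2 scale, and so were monocyte and neutrophil markers. Erythroid (median 0.31), B cell progenitor and haematopoietic progenitor markers were higher. Among the single genes named by the rule, which asks for a mean normalized count of at least 20, the largest changes were in Col6a4, Mst1r and Rpl29 on chromosome 9 close to Trex1 and in Aldh1a3 on chromosome 7. By the authors' deposited table, 77 genes (0.534% of those tested) passed a DESeq2 adjusted p of 0.05, 25 of them higher and 52 lower in Cgas-/- marrow. Their median absolute log2 fold change was 0.763, and 29 of them differed by at least 1 on the log2 scale in the authors' deposited table. An unadjusted p under 0.05 was listed for 1276 genes (8.85%).

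Interferon-stimulated genes fell together in Cgas-/- marrow. Of the 69 measured, 65 had a log2 fold change below 0, with a median of -0.31, and limma's camera test on the deposited Wald statistics gave an adjusted p of 1.50e-22. In the authors' deposited table, 9 of them fell past a DESeq2 adjusted p of 0.05 and none rose, and 16 fell when adjusted over the list alone. Oas2, an oligoadenylate synthetase that activates RNase L, fell by 1.20 ± 0.253 on the log2 scale, a 2.30-fold difference (DESeq2 adjusted p = 0.00142, authors' deposited table). Rtp4, an interferon-induced receptor transporter, fell by 0.92 ± 0.195 in the authors' deposited table (DESeq2 adjusted p = 0.00177). The others past the test were Oasl1, Oas1a, Oas3, Ifi27, Ifi27l2a, Slfn1 and Ms4a4c, of which all but Ms4a4c are named because their values had been seen. The Oas genes are close paralogs whose reads the authors' counting could split, so single Oas values are uncertain, and Rtp4 overlaps another annotated gene on the same strand. Monocyte markers, described next, fell in the same comparison with a like median of -0.31. A list of interferon-gamma-induced GTPases and chemokines did not pass in bone marrow (median -0.22, adjusted p = 0.144 by camera), except with ranks in place of the Wald statistic (adjusted p = 0.0272). MHC class I and antigen processing genes did not pass either (median -0.10, adjusted p = 0.144).

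**Figure D1:**
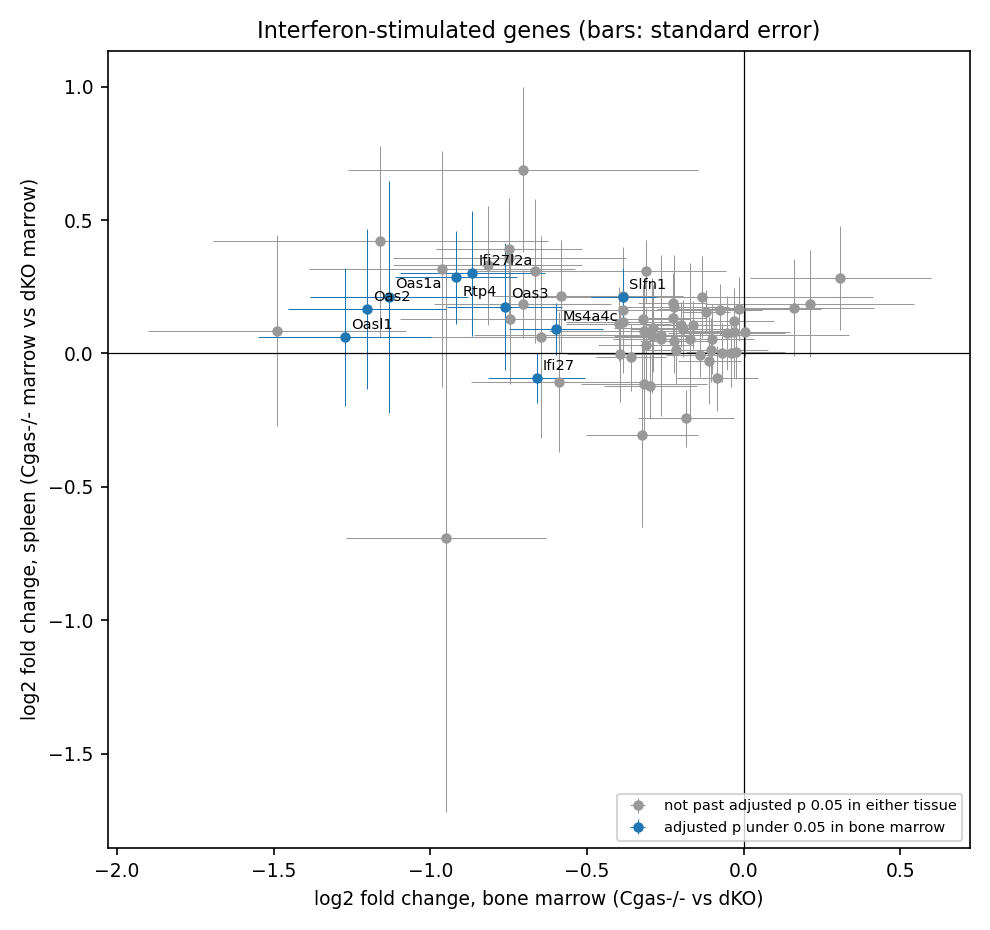
Each point is 1 of 69 interferon-stimulated genes, placed by its log2 fold change in bone marrow (x axis) and spleen (y axis), with standard errors as bars. The 9 genes past an adjusted p of 0.05 in bone marrow are blue, and 65 of the 69 lie below 0 in bone marrow and 57 above 0 in spleen.

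Markers of several blood cell types shifted in the same libraries. Monocyte markers fell, with 14 of 18 below 0, a median of -0.31 and an adjusted p of 2.74e-07 by camera. In the authors' deposited table, 4 of them passed a DESeq2 adjusted p of 0.05 (7 over the list alone), among them Ly6c2, a surface protein of classical monocytes, at -0.33 ± 0.0794 (DESeq2 adjusted p = 0.0116). Ms4a4c, which is in both the monocyte and the interferon-stimulated list, was at -0.60 ± 0.150 in the authors' deposited table (DESeq2 adjusted p = 0.0214). Genes of immature neutrophil granules had 19 of 20 members below 0 (median -0.10, adjusted p = 0.00147 by camera), and genes of mature neutrophils 13 of 16 (median -0.15, adjusted p = 0.00746). No member of these 2 neutrophil lists passed over all genes under DESeq2 in the authors' deposited table (3 mature neutrophil genes fell when adjusted over the list alone), where 2 granule genes and 4 mature neutrophil genes were lower, and 2 mature neutrophil genes higher, at an unadjusted p under 0.05. Eosinophil, basophil and mast cell genes had a median of -0.18 (adjusted p = 0.0193 by camera). That call was lost with a preset correlation of 0.05 between genes (adjusted p = 0.0964) and with ranks (adjusted p = 0.193). The eosinophil-associated ribonucleases Ear1 (-1.05 ± 0.240) and Ear6 (-0.98 ± 0.234) were its 2 called members, both past a DESeq2 adjusted p of 0.05 in the authors' deposited table, and these too are close paralogs.

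Erythroid genes rose in Cgas-/- marrow, with 25 of 27 above 0, a median of 0.31 and an adjusted p of 7.66e-12 by camera. The adult beta-globin gene Hbb-bt was at 0.84 ± 0.223 (DESeq2 adjusted p = 0.0370) in the authors' deposited table. It was among the list's 2 calls over all genes, against 8 over the list alone. The globin genes are near-identical copies, so their single values are uncertain. B cell progenitor genes rose (14 of 18 above 0, median 0.25, adjusted p = 1.60e-04 by camera). Dntt, the polymerase that adds untemplated nucleotides to V(D)J joints, was 1.56-fold higher at 0.64 ± 0.166 (DESeq2 adjusted p = 0.0311, authors' deposited table), and the surrogate light chain gene Vpreb1 had 0.76 ± 0.215 without passing (DESeq2 adjusted p = 0.0638, authors' deposited table). Haematopoietic progenitor genes rose (16 of 19 above 0, median 0.21, adjusted p = 0.00147 by camera). The cytokine receptor gene Flt3, at 0.72 ± 0.153, was their 1 call (DESeq2 adjusted p = 0.00177) in the authors' deposited table, where Gata2 had 0.31 ± 0.145 (DESeq2 adjusted p = 0.508). Flt3 is also in the dendritic cell list, which did not pass (adjusted p = 0.144 by camera), and whose next member Wdfy4 had 0.13 ± 0.0948 in the authors' deposited table. Thbs1, in the megakaryocyte and platelet list, was at 0.71 ± 0.134 (DESeq2 adjusted p = 1.15e-04) while the platelet chemokine gene Ppbp was at -0.44 ± 0.405 in the authors' deposited table. That list did not pass (adjusted p = 0.801 by camera), and its median of -0.07 and the direction of its test, upward, differ in sign, and with ranks the direction is downward. Of the 29 lists, 8 passed in bone marrow, 3 upward and 5 downward. A correlation between genes could not be estimated from these tables, and with a preset of 0.2 the interferon-stimulated, erythroid and monocyte lists kept their calls (3 of 8).

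Of the 12 genes named for their large changes in bone marrow, 6 lay near Trex1, Trex1 included. In the authors' deposited table, Rpl29, a ribosomal protein gene at 106429454 to 106431568 on chromosome 9, was 4.14-fold higher in Cgas-/- marrow (2.05 ± 0.0874, DESeq2 adjusted p = 1.25e-117). Dusp7 (1.40 ± 0.211) and Bfsp2 (1.35 ± 0.330) on chromosome 9 were also higher in the authors' deposited table, as were the mitochondrial transfer RNA gene mt-Tq (1.06 ± 0.231) and Tmem56 on chromosome 3 (DESeq2 adjusted p = 0.0120). Among genes that fell in the authors' deposited table, the collagen gene Col6a4 (-5.91 ± 0.915) and the receptor gene Mst1r (-2.34 ± 0.472) lie on chromosome 9, at 105989454 to 106096783 and 107906873 to 107920383. Aldh1a3, a retinaldehyde dehydrogenase gene on chromosome 7 (66390890 to 66427517), was 7.25-fold lower at -2.86 ± 0.267 in the authors' deposited table (DESeq2 adjusted p = 5.95e-23). Wdfy1 on chromosome 1 (-1.48 ± 0.145), the monocyte receptor gene Cd300e (-1.68 ± 0.460) and the histone gene Hist1h4m (-1.50 ± 0.325) were the other named falls in the authors' deposited table, each past a DESeq2 adjusted p of 0.05. Hist1h4m has near-identical copies and Rpl29 has processed pseudogenes, so both values are uncertain. Larger fitted changes were listed for 3 processed pseudogenes chosen after their values were seen, Gm8210 and Gm13841 (both -10.21 ± 1.04, with all values shared) and Gm14036 (-8.11 ± 1.12), in the authors' deposited table, and fitted changes of this size give no bound on the true fold. In all, 14 of the 77 called genes lay within 10 Mb of Trex1, and 62 genes were called outside the 10 Mb windows around Trex1 and Cgas, 16 higher and 46 lower.

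**Figure D2:**
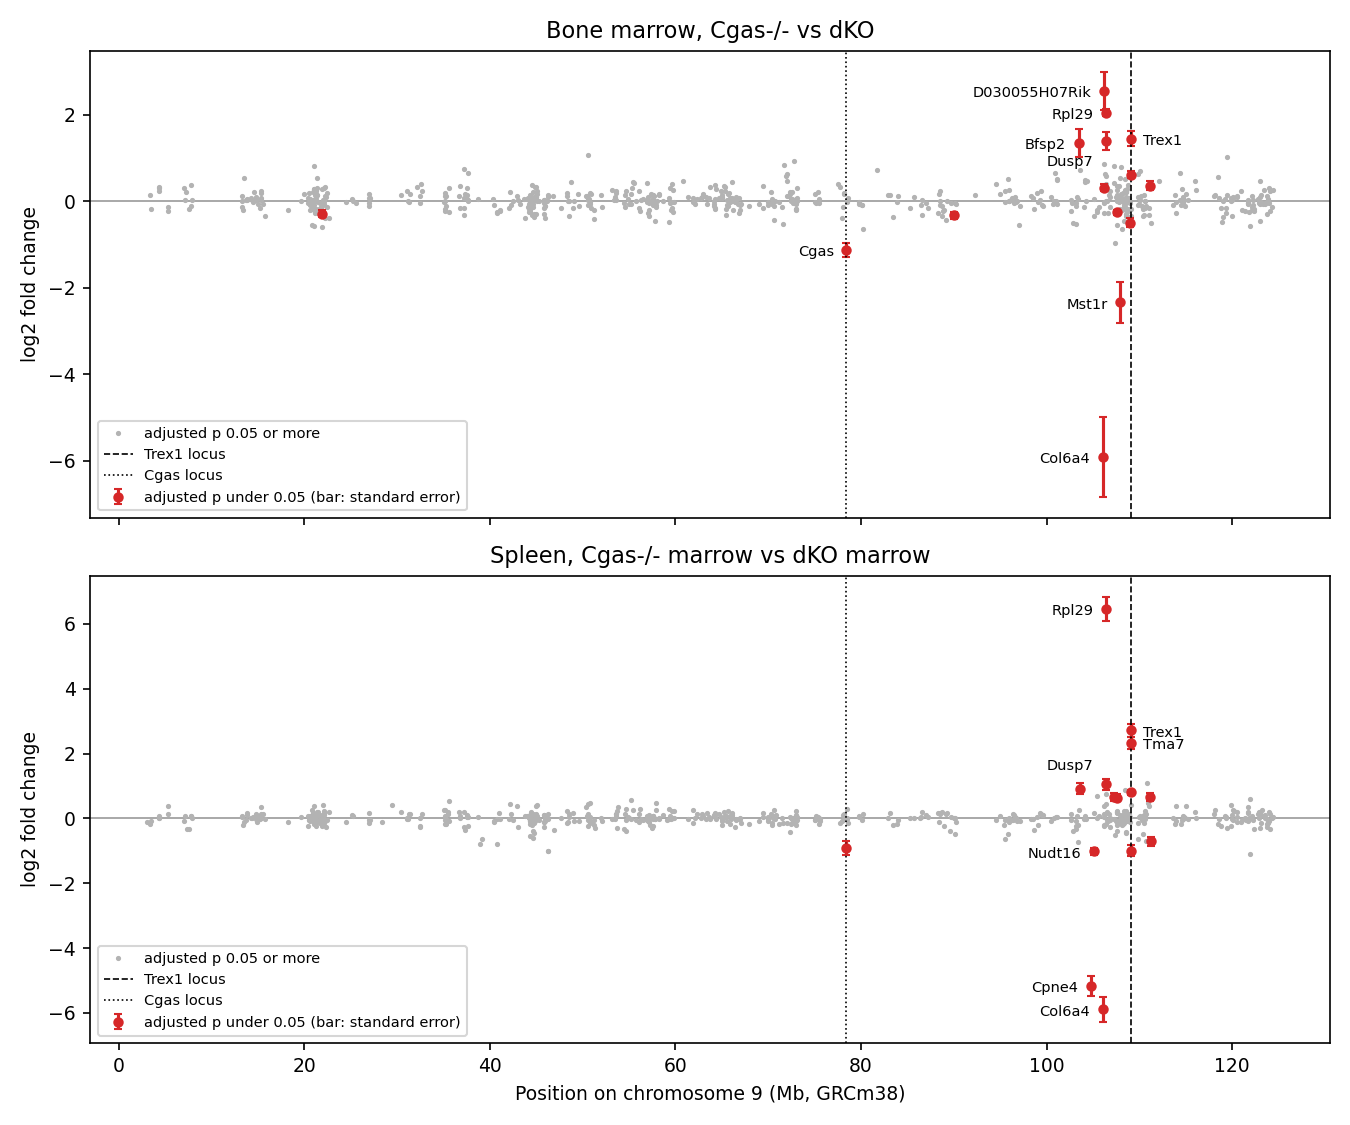
Log2 fold changes of the genes reported, with a mean normalized count of at least 20, along chromosome 9 (GRCm38), for bone marrow (top) and spleen (bottom). Red points passed an adjusted p of 0.05, with standard errors as bars, and they gather around the Trex1 locus, while Cgas is the 1 called gene within 10 Mb of itself.

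In spleen, all recipients were dKO and the transplanted marrow differed. Erythroid genes were lower (median log2 fold change -0.96) and immediate early genes higher (median 0.33) in recipients of Cgas-/- marrow. Interferon-stimulated genes as a group were slightly higher (median 0.11). Most single genes that passed were on chromosome 9 near Trex1 or on the Y chromosome. By the authors' deposited table, 29 genes (0.133%) passed a DESeq2 adjusted p of 0.05, 12 higher and 17 lower. Of these, 16 lay within 10 Mb of Trex1, Cgas was another, and 5 were on the Y chromosome, which left 7 elsewhere, 1 higher and 6 lower. An unadjusted p under 0.05 was listed for 660 genes (3.02%).

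Of 69 measured interferon-stimulated genes, 57 had a log2 fold change above 0 in spleen, with a median of 0.11 and an adjusted p of 2.38e-06 by camera. No member passed the DESeq2 test in the authors' deposited table, over all genes or over the list alone, and at an unadjusted p under 0.05 there were 4 higher and 1 lower. This call was kept up to a preset correlation of 0.08 between genes and lost at 0.2 (adjusted p = 0.385). MHC class I and antigen processing genes rose as a list, with 21 of 24 above 0, a median of 0.09 and an adjusted p of 1.11e-05 by camera. T cell genes (23 of 24 above 0, median 0.09, adjusted p = 4.00e-05) and ribosomal protein genes (16 of 25, median 0.09, adjusted p = 1.11e-05) rose by similar amounts by camera. None of the members of these 3 lists passed the DESeq2 test on its own in the authors' deposited table. At an unadjusted p under 0.05, 2 class I genes, 3 T cell genes and 6 ribosomal protein genes were higher there, and none was lower. H2-Q and other class I genes are paralogs, so their single values are uncertain.

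Immediate early genes, which cells induce within minutes of a stimulus or of dissociation, rose in spleens with Cgas-/- marrow (16 of 20 above 0, median 0.33, adjusted p = 1.83e-16 by camera). In the authors' deposited table, Fos, a subunit of the transcription factor AP-1, was 2.12-fold higher at 1.09 ± 0.158 (DESeq2 adjusted p = 8.30e-09) and was the 1 call over all genes, against 8 over the list alone. Junb, another AP-1 subunit gene, had 0.50 ± 0.128 (DESeq2 adjusted p = 0.0613) in the authors' deposited table.

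Erythroid genes fell in the same spleens, with all 27 measured members below 0, a median of -0.96 and an adjusted p of 2.72e-16 by camera. None passed the DESeq2 test over all genes in the authors' deposited table, 1 did over the list alone, and 7 were lower at an unadjusted p under 0.05. Genes of immature neutrophil granules also fell (18 of 21 below 0, median -0.52, adjusted p = 0.00455 by camera), with 2 lower at an unadjusted p under 0.05 and none past the DESeq2 test in the authors' deposited table. In all, 13 lists passed in spleen, 6 upward and 7 downward, and 7 of them kept their call with a preset correlation of 0.05. With 0.2, the immediate early and erythroid lists kept theirs (2 of 13).

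**Figure D3:**
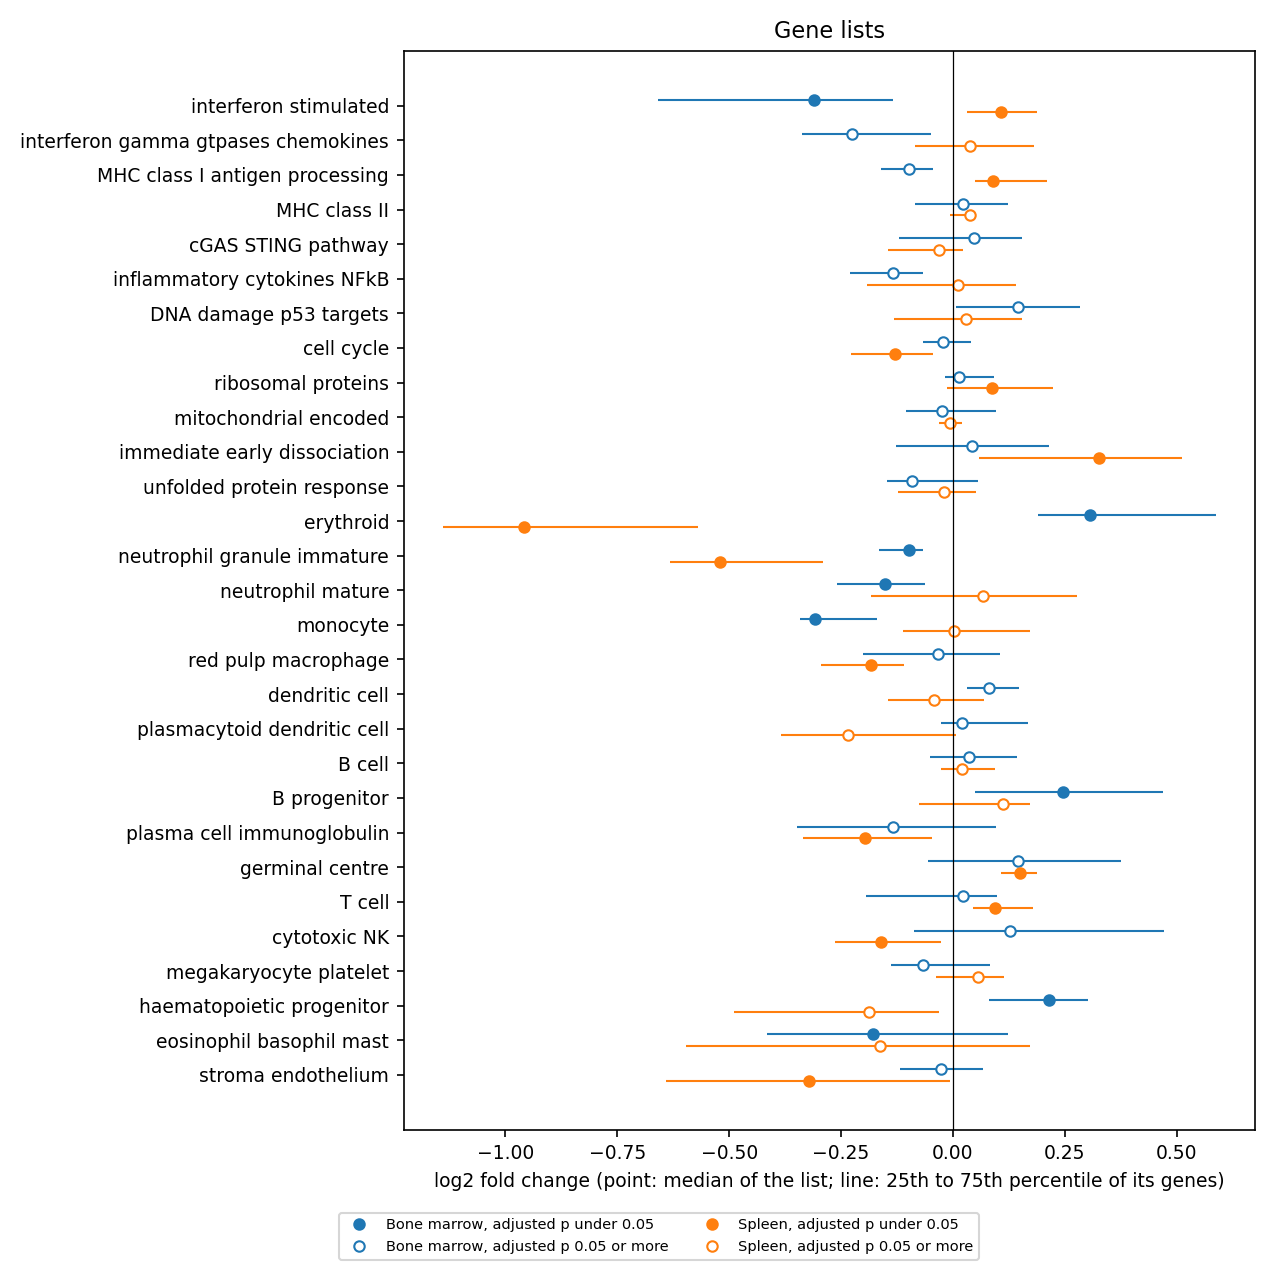
Median log2 fold change (x axis) of each of 29 gene lists in bone marrow (blue) and spleen (orange), with lines from the 25th to the 75th percentile of the list's genes. Filled points passed an adjusted p of 0.05 by camera, 8 lists in bone marrow and 13 in spleen, and erythroid genes lie at 0.31 in bone marrow and at -0.96 in spleen.

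Among single genes in spleen, Rpl29 was highest, at 6.45 ± 0.373 in the authors' deposited table (DESeq2 adjusted p = 6.59e-63). Tma7, a translation machinery gene that starts 0.0166 Mb after the start of Trex1, was at 2.33 ± 0.191 and Dusp7 at 1.05 ± 0.169 in the authors' deposited table, both on chromosome 9. The lowest called genes off the Y chromosome were Col6a4 (-5.89 ± 0.374) and Cpne4 (-5.16 ± 0.311) on chromosome 9 and Aldh1a3 (-5.42 ± 0.395) on chromosome 7, in the authors' deposited table. The Y-linked genes Eif2s3y (-5.28 ± 0.573), Uty (-5.09 ± 0.633) and Ddx3y (-4.76 ± 0.481) were as low in the authors' deposited table, each past a DESeq2 adjusted p of 0.05. Fitted fold changes of this size depend on a group with few reads and give no bound on the true fold.

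The calls of the 2 tissues overlapped. Of 13853 genes listed for both, 69 were called in bone marrow and 23 in spleen, and 12 in both, all 12 in the same direction. Per direction, 6 genes were higher in both, where independent lists would share 0.0199 (Fisher's exact test, two-sided, p = 8.30e-15). Likewise 6 were lower in both, where 0.0381 would be shared (Fisher's exact p = 6.56e-13). Without genes within 10 Mb of Trex1 or Cgas, 0 genes were higher in both (Fisher's exact p = 1) and 3 lower (Fisher's exact p = 4.03e-07). Besides Trex1 and Cgas, 7 of the 12 lay within 10 Mb of Trex1, among them Rpl29, Dusp7, Shisa5, Lrrfip2, Col6a4 and Cpne4. The remaining 3 were Aldh1a3, Wdfy1 and Rell1, a receptor gene on chromosome 5 that was at -0.32 ± 0.0813 in bone marrow and -0.89 ± 0.126 in spleen in the authors' deposited tables. These names were listed after their values were seen. Across all genes the log2 fold changes of the 2 tissues were almost unrelated (Spearman's rho 0.0419 across genes, which are not independent replicates).

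The difference between the tissues was tested directly, as the spleen log2 fold change minus that of bone marrow, since the comparisons share no library. Interferon-stimulated genes differed, with 65 of 69 higher in the spleen comparison, a median difference of 0.36 and an adjusted p of 2.49e-28 by camera. Rtp4 was the 1 member past the test of single genes, with a difference of 1.20 ± 0.262 (adjusted p = 0.00799 by a two-sided z test of the authors' deposited DESeq2 estimates). Erythroid genes differed the other way, with 27 of 27 lower in the spleen comparison, a median difference of -1.34 and an adjusted p of 2.49e-28 by camera. Fos differed by 1.20 ± 0.236 (adjusted p = 0.00101). Over all genes 8 passed, 6 of them with a higher value in spleen, and 669 (4.83%) had an unadjusted p under 0.05. The comparisons differ in tissue, in transplantation and in which cells carry which genotype, and the difference does not separate these.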

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

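The tests of low counts, of linkage among genes called in both tissues, of scaling for the interferon-stimulated genes of both tissues, and of monocytes and linked members for those of bone marrow were chosen after the result was seen, and the other tests before. Results stand here because the log2 fold change in spleen differed from that in bone marrow by a test of the difference (z per gene from the authors' deposited tables, cameraPR per list, both with Benjamini-Hochberg adjustment). Single genes were higher in the spleen comparison for Rpl29 (difference 4.40, adjusted p = 8.10e-27), Tma7 (2.52, adjusted p = 2.01e-29), Trex1 (1.26, adjusted p = 0.00434), Rtp4 (1.20, adjusted p = 0.00799), Fos (1.20, adjusted p = 0.00101) and Rassf1 (1.19, adjusted p = 0.00230). Aldh1a3 was lower (-2.56, adjusted p = 3.47e-04).

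Of the 29 lists, 14 differed, 8 upward and 6 downward. The median differences were 0.358 for interferon-stimulated genes, 0.339 for interferon-gamma-induced GTPases and chemokines, 0.186 for MHC class I, 0.176 for inflammatory cytokines, 0.0665 for ribosomal proteins, 0.223 for immediate early genes, 0.208 for monocyte markers and 0.176 for T cell genes. They were -0.121 for the cell cycle, -1.34 for erythroid genes, -0.381 for immature neutrophil granules, -0.272 for plasmacytoid dendritic cells, -0.287 for cytotoxic and NK genes and -0.452 for haematopoietic progenitors. The adjusted p was 0.0274 for cytotoxic and NK genes and 0.0478 for the interferon-gamma, inflammatory, cell cycle, ribosomal, neutrophil granule, plasmacytoid and T cell lists, and these 8 lost their call with a preset correlation of 0.05. Planned settings ended 7 of the 8 each, a mean of at least 20 all but the cell cycle and subtraction of the median all but cytotoxic and NK genes. Leaving out genes near Trex1 or Cgas removed 3 members of the neutrophil granule list. Its difference then lost its call (adjusted p = 0.0901 by camera). Its calls within bone marrow (0.00489) and spleen (0.00923) were kept. With 0.2, MHC class I (adjusted p = 0.159), immediate early (0.159), monocyte (0.110) and haematopoietic progenitor genes (0.272) lost theirs too, which left the interferon-stimulated and erythroid lists, 2 of 14.

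Calls clustered within 10 Mb of Trex1 or Cgas, pooled, with an odds ratio of 10.8 in bone marrow (Fisher's exact p = 2.36e-09) and 64.6 in spleen (Fisher's exact p = 2.77e-19), all near Trex1 (13 of 192 and 15 of 266 genes) besides the targets, and 7 of the genes called in both tissues besides the targets lay within 10 Mb of Trex1 against 3 elsewhere (Fisher's exact p = 8.48e-12). No gene near Cgas other than Cgas was called, and low counts are argued against as the whole cause, since 1 of the 12 genes called in both tissues had a mean under 20 in either. Passenger sequence of another strain, kept around the Trex1 allele when it was bred onto C57BL/6, is a candidate explanation, and in bone marrow 3 of 3 called processed pseudogenes, Gm8210, Gm13841 and Gm14036 (chosen after their values were seen), match Rpl29 at 99.4% identity and moved opposite to it (2 distinct measurements, since Gm8210 and Gm13841 share all values), which may reflect reads of a variant Rpl29 placed on them. For Aldh1a3, Wdfy1 and Rell1, off chromosome 9, a substrain difference was tested on Nnt and Entpd4, which like Wdfy1 and Ide differ between C57BL/6J and C57BL/6N, and 0 of the 3 tests run passed a two-sided normal p of 0.05 (4 were planned, but Entpd4 was not analysed here in spleen), while in the authors' deposited tables Wdfy1 fell in both tissues and Ide fell in spleen (-0.39 ± 0.0941) and had -0.14 ± 0.144 in bone marrow without passing, so this stays open. An effect of the Cgas, Trex1 or Sting1 genotype on these genes is the biological explanation and was not tested.

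As lists, interferon-stimulated genes moved in opposite directions, lower in Cgas-/- marrow and slightly higher in spleens with Cgas-/- marrow, where no single member passed the DESeq2 test in the authors' deposited table (4 higher and 1 lower at an unadjusted p under 0.05). Scaling between libraries moves all genes alike, so it would not set the list apart from the others. By camera the list differed from them, with an adjusted p of 1.50e-22 in bone marrow and 2.38e-06 in spleen, the second lost with a preset correlation of 0.2. That is the test that called the lists, so it is no separate evidence against scaling. In bone marrow only 1 of the 69 members lay near a target, which argues against linked members as the cause. Leaving that member out could hardly have ended the call (adjusted p = 3.45e-24 by camera without it). A lower share of monocytes stays open in bone marrow. The list's median minus that of 17 monocyte markers was -0.00822 (one-sided permutation p = 0.499 across genes, which are not independent). This test compares only the middle of each list. The 25th percentile was -0.66 for interferon-stimulated genes and -0.34 for all 18 monocyte markers, and the means were -0.40 and -0.28. Whether a lower share of monocytes could reach the larger falls was not tested. In spleen a different mix of cell types stays open as well. The planned test set the list's median against the largest median of a cell type list, -0.96 for erythroid genes, and gave a ratio of 0.112. Any small shift would meet this rule whatever its cause, so the test cannot decide. The biological explanation in the design, that cGAMP from dKO tissue might reach STING in Cgas-/- donor cells, was not tested here and stays open beside the mix of cell types. A difference in sex between the spleen groups, raised by Y-linked genes below, would coincide with marrow genotype. Its effect on the lists was not tested.

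Rpl29 and Tma7 had far higher log2 fold changes in spleen than in bone marrow. Counting that shares reads with processed pseudogenes differently in the tables was tested by the share of summed means in processed pseudogenes. This share was 0.173% over 297 genes in bone marrow and 1.99% over 1788 in spleen, a ratio of 0.0871. Among spleen genes with at least the smallest bone marrow mean, the share was 1.94%. The lower means listed for spleen therefore do not account for the ratio. A larger share in bone marrow had been predicted and the value came out opposite, so the planned test went against this explanation. After the result was seen, that direction was judged wrong to fix. Reads placed on pseudogenes in dKO libraries, as the called Rpl29 pseudogenes of bone marrow might hold, would enlarge the Rpl29 fold. In spleen, where the Rpl29 fold was larger, no processed pseudogene was called. Since this reading came after the result and was not tested, the explanation stays open. Other differences in counting between the tables were not tested. No biological explanation was tested.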

How the results depend on the processing

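The settings that leave out linked or Y-linked genes, count identical genes once, or use a preset correlation of 0.2 (and 0.05 for the difference) were chosen after seeing the data, and the others were planned. Bone marrow calls (77) numbered 32 at an adjusted p of 0.01, 124 at 0.1 and 29 with an absolute log2 fold change of at least 1, and 71 to 81 with low genes or identical genes left out, 62 without linked genes. Spleen calls (29) numbered 19 with an absolute log2 fold change of at least 1, 12 without genes near Trex1 or Cgas and 7 without these and Y-linked genes, and 24 to 34 otherwise. Of 8 lists in bone marrow, 3 passed with a preset correlation of 0.2, and of 13 in spleen, 7 passed with 0.05 and 2 with 0.2, where the spleen interferon-stimulated list had an adjusted p of 0.385 by camera. A larger preset widens the null by construction. Without linked genes, 4 of 8 genes differed between tissues and 3 of 12 calls were shared, fewer by construction. Lists without a call turned direction (adjusted p by camera) with ranks for platelet genes in bone marrow (0.636), and in spleen for cGAS and STING (0.395) and unfolded protein genes (0.936). With a mean of at least 20, the spleen mitochondrial (0.869) and unfolded protein lists (0.620) and the difference for mitochondrial (0.999), B cell (0.875) and germinal centre genes (0.905) turned, and with the median subtracted the spleen unfolded protein list (0.980) and the B cell difference (0.978). The causes were not tested. Of the named genes, 9 lost their call at 0.01 and 2 gained one at 0.1. No paired analysis was possible because the tables hold no values per library. For the same reason leaving out replicates, another count tool, no filter on counts, other pseudocounts, an estimated correlation, other splits of the samples and a search for single deviating libraries were not run. Depth per library is unknown, and low genes are limited most, with a median standard error of 0.835 in spleen below a mean of 20 in the authors' deposited table.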

Other observations

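The test of Y-linked genes below was planned before its result was seen, and the genes named here were chosen after their values were seen. In spleen, further lists passed by camera with small shifts and no member past the DESeq2 test in the authors' deposited table. Plasma cell genes fell (16 of 20 below 0, median -0.20, adjusted p = 0.0130), as did cytotoxic and NK genes (21 of 25, median -0.16, adjusted p = 0.0189) and red pulp macrophage genes (22 of 24, median -0.18, adjusted p = 0.0199). Cell cycle genes (24 of 32 below 0, median -0.13, adjusted p = 0.0238) and stromal and endothelial genes (19 of 25, median -0.32, adjusted p = 0.0263) fell too, and germinal centre genes rose (10 of 13 above 0, median 0.15, adjusted p = 0.0460). These 6 calls were lost with a preset correlation of 0.05, with adjusted p from 0.0829 to 0.136 by camera. At an unadjusted p under 0.05, 3, 1, 0, 1, 2 and 0 members of these lists passed in the listed direction.

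Other single genes fell in Cgas-/- marrow. The lysozyme gene Lyz2 was 1.48-fold lower (-0.56 ± 0.0892, DESeq2 adjusted p = 3.76e-07) in the authors' deposited table. The cytokine receptor gene Csf2rb (-0.42 ± 0.0875), the integrin gene Itgb2 (-0.32 ± 0.0802) and the Fc receptor subunit gene Fcer1g (-0.31 ± 0.0759) were lower in the authors' deposited table as well, each past a DESeq2 adjusted p of 0.05.

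Away from the targets and the Y chromosome, 7 genes passed in spleen, of which Fos was higher and 6 were lower. Among these, Rell1 (-0.89 ± 0.126) and 5830416I19Rik (-2.43 ± 0.328) in the authors' deposited table are neighbours on chromosome 5, at 63908897 to 63968897 and 64044978 to 64050228. The peptide transporter gene Slc15a2 was at -1.27 ± 0.191 and the insulin-degrading enzyme gene Ide at -0.39 ± 0.0941 (DESeq2 adjusted p = 0.0317) in the authors' deposited table. Aldh1a3 and Wdfy1 (-1.10 ± 0.120) complete them in the authors' deposited table.

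Y-linked genes fell in spleens with Cgas-/- marrow, where Kdm5d had -5.38 ± 0.823 in the authors' deposited table. Xist had 0.45 ± 0.126 there, which did not pass over all genes (DESeq2 adjusted p = 0.192, unadjusted p = 3.08e-04). More male cells in the group with dKO marrow is a candidate explanation. It predicts that X-linked genes escaping inactivation are higher in the other group, and the mean of Ddx3x, Eif2s3x, Kdm5c and Kdm6a was 0.0719 ± 0.0455, above 0 but not past a two-sided normal p of 0.05. The X-linked test alone decides neither way. The fall of all 5 called Y-linked genes raised this explanation, so it is no separate test of it. Xist was higher, past 0.05 only unadjusted, the direction that more male cells in the dKO-marrow group would give. The labels used here give no sex. In bone marrow Xist had -0.10 ± 1.65 in the authors' deposited table at a mean of 3563, a wide spread for so abundant a gene that may come from libraries of both sexes within groups, which was not tested because Ddx3y, Eif2s3y, Kdm5d and Uty were not analysed here in bone marrow.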
